A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

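Yeast of strain S288C was grown in synthetic glucose medium at 30 °C with shaking at 220 rpm, exposed for 6 h, and sequenced as 3 untreated, 3 CdSe/ZnS and 3 InP/ZnS libraries, per the labels. Messenger RNA was isolated with a stranded poly(A) kit and the libraries were amplified for 15 cycles, per the labels' protocols. Poly(A) selection keeps few RNAs without a tail, so levels of ribosomal, small nucleolar and mitochondrial RNAs depend on how complete it was. The treatment text of the labels gives the InP/ZnS dose in mg/mL and repeats it for every sample, while the design text gives 100 µg/mL; the design text was followed here, and the unit remains uncertain. Per the deposited text sheets, reads were processed in Galaxy: bases below a quality of 20 were removed, 12 bases were trimmed from the 5′ end and reads under 80 bp were dropped. TopHat was used to align to the S288C genome from SGD and Cufflinks was run with the reference annotation, per the same sheets, and TopHat and Cuffdiff are named in the submitters' processing notes. Versions, the build number, strand settings and the library normalisation setting are not given in the sources used here. Whether reads were counted by strand is likewise not given, so genes that overlap or face an antisense partner are uncertain.

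The authors deposited 1 table per quantum dot, in the layout of Cuffdiff's gene-level output per the file headers. FPKM (fragments per length and per library size) were deposited by the authors as 1 value per gene and condition, which pools the libraries. The log2 fold change is the authors' deposited ratio of treated to untreated FPKM, without a pseudocount. The test score is Cuffdiff's statistic, per the file headers. The p-value and q-value are the authors' deposited ones; the smallest p was 5e-05, shared by 1834 genes with CdSe/ZnS and 1266 with InP/ZnS, and so is a limit of the method. The treated column was identified from the authors' deposited lists of higher and lower genes. Those lists held the same 606 and 2759 genes for CdSe/ZnS, and 1522 and 1096 for InP/ZnS, as the full tables at q under 0.05. The tables held 7012 and 7042 entries, of which 6321 and 6367 were tested; 677 and 675 had too few reads and 14, in the CdSe/ZnS table, too many. No column held a single library, so no depth, library total or replicate spread was used, and no test over libraries was made. Fixed rules foresaw this case: the authors' test was the main result.

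Coordinates are those of the authors' deposited table, converted to start from 1. Of 5245 entries alone at their locus in the CdSe/ZnS table and also in the RefSeq annotation of assembly R64, 99.5% had the same start and end, and 99.6% of 5250 in the InP/ZnS table. The annotation served for gene type, synonyms and coding length; 90.2% of the tested entries in each table matched it, and 99.7% of the lengths were multiples of 3, so they hold no untranslated regions. Entries that share a locus, 18.4% and 18.3% of those tested, are marked as uncertain where named.

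A standard error was taken as the log2 fold change over the test score. From it, a 2-sided normal test with Benjamini-Hochberg adjustment was computed on fold changes as deposited, centred on the median of all genes, or freed of their trend with coding length (medians of 20 length bins, interpolated). The normal test differs from the deposited p: 970 and 1329 genes had a deposited p under 0.05 with a score too small for the normal test, and 19 and 21 genes the reverse. The difference between the quantum dots was the difference of the log2 fold changes over the root of the summed squares of both standard errors. Because the control is shared, that error is too large where the control varies. In 43 gene lists, higher and lower calls were each compared with all other tested genes by 2-sided Fisher's exact test, adjusted over 86 tests, and the list median was placed among 10000 random lists matched in 20 expression bins. Genes are not independent of each other, so these p-values describe the lists in these libraries.

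Groups, thresholds, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Per comparison, the rule took the 10 protein-coding genes with the largest fold change in each direction. These had to be past the threshold, at 10 FPKM or more in either condition. It also took up to 4 genes per list that passed, by smallest q, with ties going to the larger absolute log2 fold change. Many genes share the smallest q, so the genes named for a list lean towards its largest folds. Where measured, the rule also took CUP1-1, CUP1-2, YCF1, ZRT1, FET3, MET17, HSP12, HSP26, CTT1, SOD1, TRX2 and GSH1. No value is given here for MET17. The rule further took the 5 largest differences between the quantum dots per direction, and 10 genes called in opposite directions. Alternatives were q under 0.01, an absolute log2 fold change of at least 1, a floor of 1 or 10 FPKM, a new adjustment over all genes with a value, and centring; the uncentred normal test, removal of the length trend, the limit on the standard error and, between the quantum dots, centring were added after the data were seen.

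The steps were tested on simulated data. With 100 of 6290 genes changed by each size, the test of the difference recovered 25.0% at a log2 change of 1 and 92.0% at 2, and called 0 unchanged genes. The normal test recovered 72.0% and 94.0% for CdSe/ZnS and 70.0% and 96.0% for InP/ZnS, with 6 and 10 unchanged genes called. The simulated noise was normal with the same implied standard errors that the tests use, and no shift common to all genes was put in. These rates therefore show that the steps run as meant, not how often the tests err on the real fold changes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.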

Results

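RNA was sequenced from the budding yeast Saccharomyces cerevisiae, laboratory strain S288C, grown in synthetic glucose medium to mid-log phase at an optical density of 0.3 to 0.6. The design text names 3 conditions, each held for 6 h: no treatment, CdSe/ZnS quantum dots (dose 10 µg/mL) and InP/ZnS quantum dots (dose 100 µg/mL). Quantum dots are semiconductor nanocrystals; both kinds carry a zinc sulfide shell, around a core of cadmium selenide or of indium phosphide. The labels list 3 libraries per condition, 9 in all, and do not say whether they came from separate cultures, so the tests measure only the spread between these libraries, which may be technical. The values analysed were 1 FPKM per gene and condition with the authors' fold change and test, so no value per library and no library total was used and the depth is unknown. The error given with a fold change is the standard error implied by the authors' own test statistic; its median over genes was 0.246 with CdSe/ZnS and 0.246 with InP/ZnS, on the log2 scale.

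The first comparison asked which transcripts differed between cells exposed to CdSe/ZnS quantum dots and untreated cells. Heat shock proteins and chaperones rose with CdSe/ZnS, while the genes of cytosolic and mitochondrial ribosomal proteins, the proteasome and the endocytic actin patch fell. SPS100, a spore wall protein gene, fell by 3.70 on the log2 scale in the authors' deposited table (implied standard error 0.25), from 207 to 15.9 FPKM. TIR1, which encodes a cell wall mannoprotein of anaerobic growth, rose from 7.65 to 63.2 FPKM in the authors' deposited table, an 8.26-fold increase. By the authors' q under 0.05, 606 genes were higher and 2759 lower of 6321 tested.

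More genes fell than rose. The median log2 fold change of all tested genes was -0.35, a fold of 0.786, with quartiles of -0.77 and 0.06. Of the calls, 18.0% were higher and 82.0% lower; with each fold change taken relative to that median and tested against its implied standard error in a normal test, 752 genes were higher and 862 lower, or 46.6% and 53.4%. Short genes fell further than long ones, with a Spearman correlation of 0.34 between coding length and fold change across 5704 genes, which are not independent replicates. The median was -0.82 for genes of up to 300 bp and 0.05 for those over 3000 bp.

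**Figure D1:**
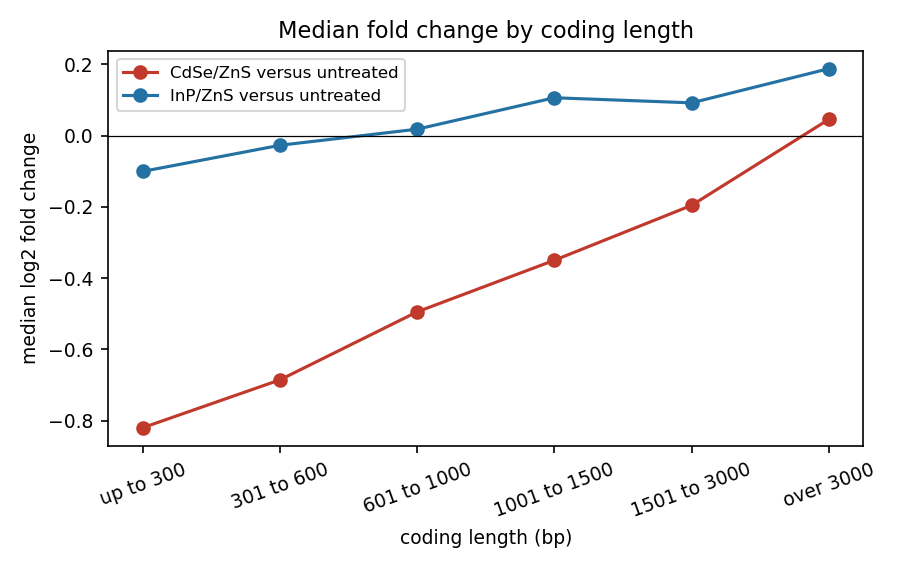
Median log2 fold change against untreated cells (vertical axis) of tested genes grouped by coding length in bp (horizontal axis), for CdSe/ZnS (red) and InP/ZnS (blue). With CdSe/ZnS the medians run from -0.82 in the shortest genes to 0.05 in the longest, and with InP/ZnS from -0.10 to 0.19.

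The genes that fell furthest with CdSe/ZnS included 2 short reading frames of very high level in untreated cells. In the authors' deposited table YDL012C (chromosome IV, 431108 to 431517) fell from 6730 to 610 FPKM and YPR145C-A (chromosome XVI, 824690 to 824926) from 6324 to 679 FPKM. YPT53, a Rab GTPase gene of endocytic transport on chromosome XIV (449868 to 450530), had a log2 fold change of -2.89 in the authors' deposited table, or -2.55 relative to the median of all genes. PUN1, a plasma membrane protein gene, and YLR194C, a cell wall protein gene, had log2 fold changes of -2.72 and -2.68 in the authors' deposited table. YOL014W fell by 2.80 and BSC1 fell by 2.98 on the log2 scale in the authors' deposited table, each with q = 0.000173, the smallest it holds. YDR210W and YMR316C-A, at -3.21 and -2.63 in the authors' deposited table, each share a locus with another entry and are uncertain, and the second passed the normal test as deposited but not relative to the median.

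Among the genes that rose furthest with CdSe/ZnS, GPH1, glycogen phosphorylase, rose 3.84-fold and HXK1, a hexokinase, 3.33-fold in the authors' deposited table; both share a locus with other entries. HXT7, a high-affinity hexose transporter, rose 3.50-fold in the authors' deposited table, from 55.9 to 196 FPKM, and is nearly identical in sequence to HXT6, so reads of this pair are uncertain. IDP1 and OAR1, enzymes of mitochondrial metabolism, rose 3.35-fold and 3.20-fold in the authors' deposited table. YOR192C-C and YHR130C, 2 small open reading frames, had log2 fold changes of 2.36 and 1.72 with implied standard errors of 0.84 and 0.84 in the authors' deposited table. YHR130C did not pass the normal test, either as deposited or relative to the median, where it stood at 2.07. AI1 and AI2, reading frames within introns of the mitochondrial COX1 gene that overlap other entries, stood at 0.186 and 0.130 FPKM untreated and 61.6 and 31.0 FPKM with CdSe/ZnS in the authors' deposited table.

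Lists fixed before the data were examined gave 12 groups with more calls in 1 direction than the other tested genes, of 43 lists in 86 tests. In the ribosomal protein list 117 of 135 members fell (119 adjusted over the list alone) and 0 rose, with an adjusted p of 9.26e-24 by Fisher's exact test. Their median log2 fold change was -0.84, or -0.49 relative to all genes, below all of 10000 random lists matched on expression. With the trend with coding length removed before the normal test the median was -0.16 and 14 members were lower, which ended the call (adjusted p = 0.856, Fisher's exact test). That median still lay below the central 95% of random lists, which ran from -0.06 to 0.13. RPL34A fell by 1.86, RPL37B by 1.77 and RPL31A by 1.64 on the log2 scale in the authors' deposited table; many of these genes have a near-identical copy, which makes the value of a single one uncertain. Of 71 mitochondrial ribosomal protein genes, 62 fell (66 adjusted over the list alone) and 0 rose (adjusted p = 5.5e-13, Fisher's exact test), including RSM19, which fell by 2.09 in the authors' deposited table, and RSM27, which fell by 1.73. With that trend removed their median was -0.37 and 16 were lower (adjusted p = 0.087, Fisher's exact test), the median again lying below the central 95% of random lists.

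The proteasome, which degrades tagged proteins, had 29 of 34 genes lower (30 adjusted over the list alone) and 0 higher (adjusted p = 1.01e-05, Fisher's exact test). PRE6 fell by 1.62, PRE9 by 1.31 and PUP1 by 1.26 on the log2 scale in the authors' deposited table. Of the endocytosis and actin patch genes, 22 of 27 fell (22 adjusted over the list alone) and 1 rose (adjusted p = 0.00101, Fisher's exact test), among them ENT1 and ENT2, epsin genes, at -1.50 and -1.36 in the authors' deposited table, and VRP1 and ARC15, both at -1.31; ENT1 and VRP1 share a locus with another entry and are uncertain. Nuclear genes of the respiratory chain and ATP synthase had 26 of 37 members lower (26 adjusted over the list alone) and 1 higher (adjusted p = 0.00711, Fisher's exact test), including COX8 at -1.42 and COX9 at -1.16 in the authors' deposited table. Their median was -0.64, -0.29 relative to all genes and 0.06 once the trend with length was removed, where the direction turned.

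Heat shock proteins and chaperones had 14 of 21 members higher with CdSe/ZnS (14 adjusted over the list alone) and 1 lower (adjusted p = 5.09e-09, Fisher's exact test). Their median log2 fold change was 0.59, or 0.94 relative to all genes. SSA4, a stress-induced Hsp70 chaperone gene on chromosome V (364589 to 366517), rose from 142 to 448 FPKM in the authors' deposited table, and HSC82, which has the near-identical copy HSP82, and SSA1, which shares a locus with another entry, rose by 1.39 and 1.24 on the log2 scale. Purine synthesis genes rose in 8 of 18 cases (8 adjusted over the list alone) and fell in 5 (adjusted p = 0.00106, Fisher's exact test), with GCV2 at 1.02 and SHM2 at 0.96 in the authors' deposited table, enzymes of 1-carbon metabolism. Of 14 genes of drug efflux pumps and their regulators, the multidrug transport list, 7 rose (7 adjusted over the list alone) and 5 fell (adjusted p = 0.00106, Fisher's exact test), the transporter genes YOR1, PDR12 and PDR5 having log2 fold changes of 0.92, 0.89 and 0.72 in the authors' deposited table. YOR1 and PDR5 are known targets of Pdr1 and Pdr3, and PDR12 of War1.

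Anaerobic and hypoxic genes had 6 of 14 members higher (6 adjusted over the list alone) and 4 lower (adjusted p = 0.00711, Fisher's exact test); beside TIR1, the heme synthesis gene HEM13 rose by 1.57 on the log2 scale in the authors' deposited table. Ergosterol synthesis genes rose in 8 of 24 cases (8 adjusted over the list alone) and fell in 7 (adjusted p = 0.00711, Fisher's exact test), with ERG5 at 0.85 and ERG4 at 0.78 in the authors' deposited table. In the list of genes under nitrogen catabolite repression 7 of 21 rose (7 adjusted over the list alone) and 7 fell (adjusted p = 0.012, Fisher's exact test), and the median was -0.02, or 0.33 relative to all genes. MEP2, an ammonium permease gene, rose by 1.43, DAL3 by 1.22 and PUT2 by 1.10 on the log2 scale in the authors' deposited table. Amino acid biosynthesis genes under Gcn4 rose in 11 of 47 cases (9 adjusted over the list alone) and fell in 11 (adjusted p = 0.0183, Fisher's exact test), with the arginine genes ARG3 and ARG8 at 1.39 and 1.20 in the authors' deposited table.

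With the normal test on fold changes as deposited, chosen after the data were seen, the respiratory chain list no longer passed, with 18 members lower (adjusted p = 0.0818, Fisher's exact test). Nor did the amino acid, purine, nitrogen, ergosterol and endocytosis lists. Lists gained with that test were sulfur assimilation, mitochondrial genome, small nucleolar RNAs and sporulation for higher genes, and cell wall and core histones for lower ones. With the same test relative to the median of all genes, the proteasome list, which had 22 members lower as deposited, was lost with 9 (adjusted p = 0.154, Fisher's exact test) and the respiratory chain stayed lost with 9 (adjusted p = 0.247, Fisher's exact test). The other 5 lists passed again, the induced stress response was gained for higher genes (adjusted p = 0.00927, Fisher's exact test), and of the lists gained before, small nucleolar RNAs and sporulation no longer passed. With the trend with coding length removed before that test, also chosen after the data were seen, only the heat shock, purine and endocytosis lists passed, among the 12. Stress response, cell wall, vacuolar protein sorting and mitochondrial genome lists were gained there. A lost call did not always go with a much smaller fold. The ribosomal median did shrink, from -0.49 relative to all genes to -0.16 with the trend removed. Those of the nitrogen and multidrug lists with the trend removed are not given here. Among other lists lost there, the medians with the trend removed were -0.34 for the proteasome, 0.54 for anaerobic, 0.32 for amino acid and 0.28 for ergosterol genes. Relative to all genes they had been -0.44, 0.49, 0.37 and 0.35. These 4 lay outside the central 95% of random lists with the trend removed.

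Genes of metal handling were of interest because the cores and shells hold cadmium and zinc. Of 8 tested genes for metallothioneins and cadmium handling, 1 rose and 4 fell, and the list did not pass its test (adjusted p = 0.807 and 0.896, Fisher's exact test). CUP1-1 and CUP1-2, identical copies of the main metallothionein gene, were listed at 0 and not tested in the authors' deposited table. CRS5, another metallothionein gene, was chosen after its value was seen and fell from 1110 to 314 FPKM in the authors' deposited table, a log2 fold change of -1.82. ZRT1, the high-affinity zinc transporter gene, fell by 1.61 and FET3, a ferroxidase gene of iron uptake, rose by 0.88 on the log2 scale in the authors' deposited table. YCF1, a vacuolar transporter gene for glutathione conjugates, stood at 0.34 with q = 0.0564 in the authors' deposited table, and at 0.68 relative to the median, where it passed the normal test. Among stress genes, HSP26 fell by 1.27 and the thioredoxin gene TRX2 by 1.21 in the authors' deposited table, and SOD1 by 0.47, while HSP12, CTT1 and GSH1 did not pass (0.22, 0.07 and 0.15). SOD1 did not pass the normal test, either as deposited or relative to the median, where it stood at -0.12, and HSP12 passed it relative to the median, at 0.57.

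The other 31 lists did not pass in either direction as enriched with CdSe/ZnS. Over all 43 lists, 3 tests of higher and 5 of lower calls instead found fewer calls than among other genes (adjusted p under 0.05, Fisher's exact test). Among growth and energy lists, 3 rose and 30 fell of 69 ribosome biogenesis genes, 2 rose and 11 fell of 20 RNA polymerase I and III subunits, 2 rose and 4 fell of 14 TCA cycle genes, and 2 rose and 7 fell of 18 genes of glycolysis and fermentation. Gluconeogenesis, the glyoxylate cycle and fatty acid oxidation had 3 higher and 1 lower of 19, and hexose transporters 2 higher and 7 lower of 14. In the induced environmental stress response 7 rose and 11 fell of 30, with a median of -0.07 and 0.28 relative to all genes, and in oxidative stress defence 3 rose and 14 fell of 27. Zinc homeostasis had 5 higher and 5 lower of 17, the iron regulon 6 and 8 of 26, copper uptake 1 and 1 of 5, sulfur assimilation and methionine 6 and 8 of 26, and phosphate starvation 1 and 6 of 15. Cell wall genes had 2 higher and 18 lower of 27, seripauperins 1 and 2 of 8, endoplasmic reticulum folding genes 3 and 7 of 16, vacuolar protein sorting 3 and 34 of 60, autophagy 4 and 20 of 37, vesicle coats 1 and 9 of 18, and the vacuolar ATPase 2 and 9 of 17. Core histones had 0 higher and 7 lower of 8, cyclins and G1/S genes 2 and 10 of 17, and DNA damage genes 2 and 4 of 14. Small nucleolar RNAs had 9 higher and 1 lower of 46, with a median of 0.34, above all of 10000 random lists. That list passed with a floor of 10 FPKM (adjusted p = 0.0411, Fisher's exact test) or a log2 fold change of at least 1 required (adjusted p = 0.00874, Fisher's exact test). The mitochondrial genome list had 0 higher and 0 lower of 3, but held only 3 of the 9 tested entries of that genome, of which 4, AI1, AI2, 15S_rRNA and 21S_rRNA, were called higher. The a-specific mating genes had 1 higher and 4 lower of 7, alpha-specific ones 0 and 1 of 3, sporulation 3 and 2 of 10, and flocculation 0 and 4 of 8. The name pattern for Ty retrotransposons, which also takes other short open reading frames, had 11 higher and 64 lower of 342. Adjusted over the list alone, the counts were equal in 20 of the 31 lists and differed by at most 3 in the others, apart from the Ty pattern, with 6 and 46.

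**Figure D2:**
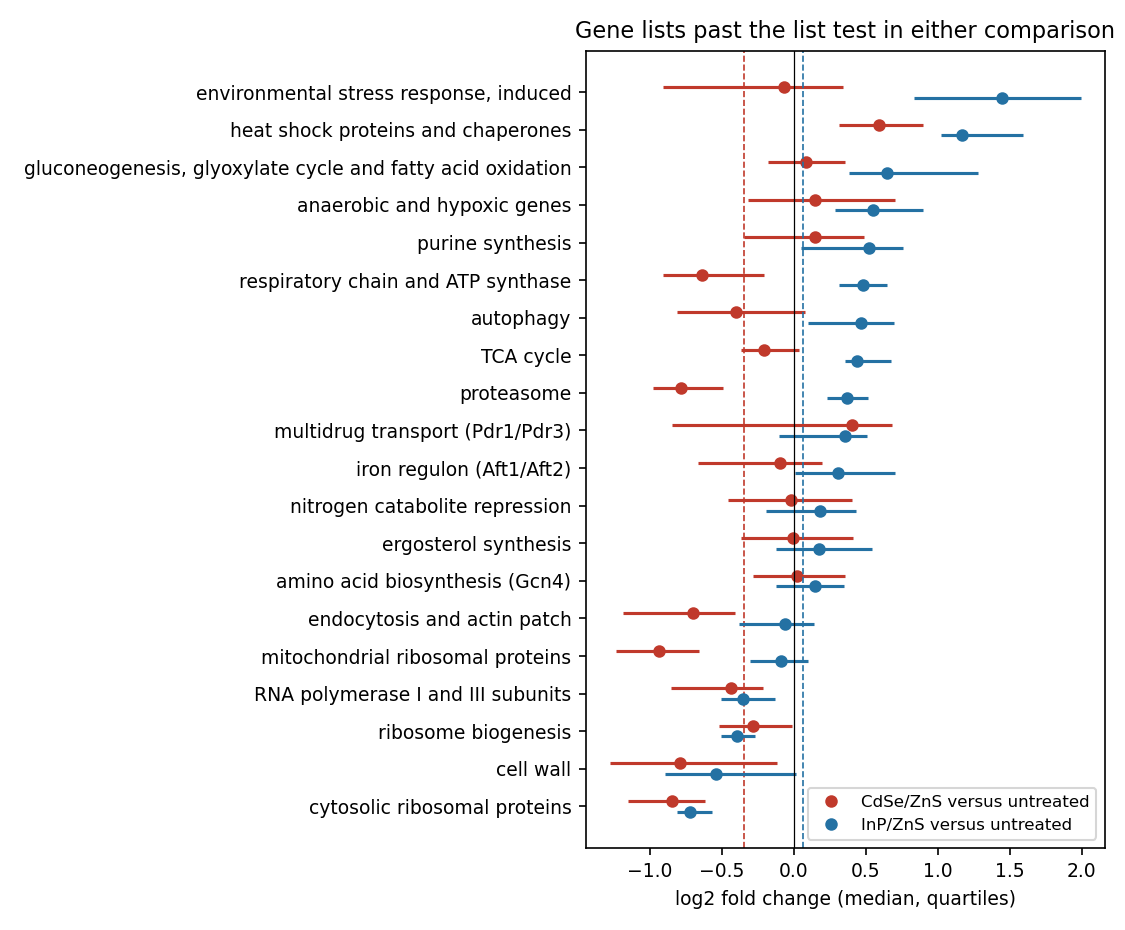
Median log2 fold change against untreated cells (points, horizontal axis) and quartiles (lines) of the tested members of each gene list that passed its test in either comparison, for CdSe/ZnS (red) and InP/ZnS (blue). Dashed lines mark the median of all tested genes, -0.35 and 0.07. Proteasome medians lie at -0.79 and 0.37 and those of the cytosolic ribosomal proteins at -0.84 and -0.72.

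The second comparison asked the same of InP/ZnS quantum dots, given at a higher dose. Genes of the induced environmental stress response, heat shock proteins, the nuclear-encoded respiratory chain and the TCA cycle rose with InP/ZnS, and those of ribosomal proteins, ribosome biogenesis and the cell wall fell. TIR1 rose 21.9-fold in the authors' deposited table, from 8.34 to 183 FPKM, with a log2 fold change of 4.45 and an implied standard error of 0.34. SPS100 fell by 2.88 on the log2 scale in the authors' deposited table, from 241 to 32.7 FPKM (implied standard error 0.25). By the authors' q under 0.05, 1522 genes were higher and 1096 lower of 6367 tested, and the median log2 fold change of all genes was 0.07.

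Among the genes that rose furthest with InP/ZnS, HXK1, a hexokinase gene, rose from 301 to 3189 FPKM in the authors' deposited table, HXT6 10.5-fold and HXT7 8.61-fold, the transporters being near-identical copies. HXK1 and GPH1 share a locus with other entries in this table too and are uncertain. GSY1, glycogen synthase, rose 9.71-fold and GPH1 and PGM2 rose 7.95-fold and 7.93-fold in the authors' deposited table. OYE3, an NADPH oxidoreductase gene on chromosome XVI (226169 to 227371), rose from 12.7 to 179 FPKM and CYC7, an isoform of cytochrome c, from 96.3 to 864 FPKM in the authors' deposited table. DAN1, a mannoprotein gene of anaerobic growth, rose from 0.828 to 17.2 FPKM with an implied standard error of 0.83 on the log2 scale in the authors' deposited table. Among those that fell furthest, YDL012C, YPR145C-A and YPT53 had log2 fold changes of -2.44, -2.39 and -2.36 in the authors' deposited table. YLR194C was at -2.23, PHO89, a sodium-phosphate cotransporter gene, at -2.15, RCN1, a calcineurin regulator gene, at -2.06, and JLP1, a sulfonate dioxygenase gene, at -2.03 in the authors' deposited table. OSW2 and BSC1 stood at -2.06 and -2.01 in the authors' deposited table.

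The induced environmental stress response had 26 of 30 members higher with InP/ZnS (26 adjusted over the list alone) and 3 lower (adjusted p = 8.24e-12, Fisher's exact test), with a median log2 fold change of 1.44. PGM2 and the glycogen branching enzyme gene GLC3 had log2 fold changes of 2.99 and 2.59 in the authors' deposited table. All 21 tested heat shock proteins and chaperones rose (21 adjusted over the list alone; adjusted p = 1.37e-12, Fisher's exact test), with a median of 1.17. SSA4 rose by 2.53, HSP42 by 1.89 and HSP82 by 1.75 on the log2 scale in the authors' deposited table; HSP82 has the near-identical copy HSC82.

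Nuclear genes of the respiratory chain and ATP synthase rose in 28 of 37 cases (29 adjusted over the list alone) and fell in 0 (adjusted p = 4.91e-10, Fisher's exact test), with a median of 0.48. NDI1, the internal NADH dehydrogenase gene, rose by 1.09 and SDH1 by 0.97 on the log2 scale in the authors' deposited table. TCA cycle genes rose in 12 of 14 cases (12 adjusted over the list alone) and fell in 0 (adjusted p = 1.46e-05, Fisher's exact test), with ACO1 at 1.12 and CIT1 at 1.10 in the authors' deposited table. In gluconeogenesis, the glyoxylate cycle and fatty acid oxidation 11 of 19 rose (14 adjusted over the list alone) and 1 fell (adjusted p = 0.00752, Fisher's exact test). ALD4, mitochondrial aldehyde dehydrogenase, rose by 2.19 and the carnitine shuttle genes CRC1 and CAT2 by 1.55 and 1.54 on the log2 scale in the authors' deposited table.

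The proteasome had 20 of 34 genes higher with InP/ZnS (24 adjusted over the list alone) and 0 lower (adjusted p = 9.57e-05, Fisher's exact test). RPN4, the transcription factor gene of the proteasome, rose by 1.06 and RPN8, a subunit of its lid, by 0.97 on the log2 scale in the authors' deposited table. Of 37 autophagy genes, 20 rose (21 adjusted over the list alone) and 2 fell (adjusted p = 0.000734, Fisher's exact test); YLR312C, YBR139W and ICY2, which the reference names as autophagy genes, stood at 1.53, 1.19 and 0.99 in the authors' deposited table, and ATG7 at 0.95. Purine synthesis genes rose in 12 of 18 cases (12 adjusted over the list alone) and fell in 2 (adjusted p = 0.000817, Fisher's exact test), with the glycine cleavage genes GCV1 and GCV2 at 1.73 and 1.42 in the authors' deposited table. The iron regulon under Aft1 and Aft2 had 13 of 26 members higher (13 adjusted over the list alone) and 4 lower (adjusted p = 0.018, Fisher's exact test), including FIT2 at 1.59 and FRE2 at 1.23 in the authors' deposited table, genes of iron uptake at the cell surface. Anaerobic and hypoxic genes rose in 8 of 15 cases (10 adjusted over the list alone) and fell in 1 (adjusted p = 0.0468, Fisher's exact test), with HEM13 at 1.04 and COX5B at 0.75 in the authors' deposited table.

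Of the genes that fell as groups, 128 of 135 cytosolic ribosomal protein genes were lower with InP/ZnS (131 adjusted over the list alone) and 0 higher (adjusted p = 9.21e-89, Fisher's exact test). Their median was -0.72, and RPL8A and RPL34A fell by 1.38 and 1.08 on the log2 scale in the authors' deposited table, again with near-identical copies in the genome. Ribosome biogenesis genes fell in 43 of 69 cases (48 adjusted over the list alone) and rose in 0 (adjusted p = 1.38e-15, Fisher's exact test), with the nucleolar genes NSR1, which shares a locus with another entry, at -1.11 and RRS1 at -0.89 in the authors' deposited table. RNA polymerase I and III subunits fell in 11 of 20 cases (13 adjusted over the list alone) and rose in 0 (adjusted p = 0.000817, Fisher's exact test), with RPC10 at -0.87 and RPA49 at -0.81 in the authors' deposited table. Cell wall genes fell in 17 of 27 cases (17 adjusted over the list alone) and rose in 4 (adjusted p = 1.17e-06, Fisher's exact test); the chitin synthase gene CHS1 fell by 1.77 and the aspartyl protease gene YPS1 fell by 1.32 on the log2 scale in the authors' deposited table.

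With the normal test on centred fold changes, which called 501 genes higher and 530 lower with InP/ZnS, 6 of these 14 lists no longer passed: respiratory chain, TCA cycle, purine synthesis, proteasome, autophagy and RNA polymerases I and III. The TCA cycle, proteasome and RNA polymerase lists, and ribosome biogenesis, were lost with the normal test on fold changes as deposited. Centring takes the median of all genes, 0.07, from every gene, so the medians of the 6 lists lost there could move only by that. In the order first named, they were 0.48, 0.44, 0.52, 0.37, 0.47 and -0.35 as deposited, and 0.41, 0.38, 0.45, 0.30, 0.40 and -0.42 relative to all genes. With a log2 fold change of at least 1 required, 4 lists still passed: stress response, heat shock, gluconeogenesis and cell wall.

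Metal handling genes did not pass as a list with InP/ZnS, 3 of 8 being higher and 3 lower (adjusted p = 0.624 and 0.303, Fisher's exact test). CRS5 stood at -0.89 and ZRT1 also at -0.89 in the authors' deposited table, and YCF1 rose by 0.57 on the log2 scale there, a call lost with the normal test, centred or not. HSP12, CTT1 and HSP26, genes of the general stress response, rose by 1.73, 1.97 and 0.96 on the log2 scale in the authors' deposited table. FET3, SOD1, TRX2 and GSH1 did not pass, with log2 fold changes of 0.27, 0.12, -0.08 and 0.03 in the authors' deposited table. CUP1-1 and CUP1-2 were again listed at 0.

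The remaining 29 lists were not enriched for the authors' calls with InP/ZnS. Over all 43 lists, 7 tests of higher and 3 of lower calls instead found fewer calls than among other genes (adjusted p under 0.05, Fisher's exact test). DNA damage genes passed as higher in the normal test, whether centred, uncentred or with the length trend removed (adjusted p = 0.028, 0.0361 and 0.0338, Fisher's exact test). Glycolysis and fermentation passed as lower in the uncentred one (adjusted p = 0.0304, Fisher's exact test), and multidrug transport as higher with a floor of 10 FPKM (adjusted p = 0.0366, Fisher's exact test). Mitochondrial ribosomal protein genes had 6 higher and 17 lower of 71, glycolysis and fermentation 2 and 6 of 18, hexose transporters 5 and 2 of 16, and oxidative stress defence 12 and 3 of 27. Zinc homeostasis had 3 higher and 2 lower of 17, copper uptake 3 and 0 of 5, sulfur assimilation and methionine 8 and 7 of 26, phosphate starvation 3 and 4 of 16, amino acid biosynthesis 9 and 5 of 47, nitrogen catabolite repression 6 and 4 of 21, and ergosterol synthesis 9 and 0 of 24. Seripauperins had 2 higher and 0 lower of 11, endoplasmic reticulum folding 3 and 0 of 16, vacuolar protein sorting 14 and 6 of 60, vesicle coats 0 and 3 of 18, endocytosis and actin patch 1 and 9 of 27, the vacuolar ATPase 1 and 1 of 17, and multidrug transport 7 and 2 of 14. Core histones had 2 higher and 2 lower of 8, cyclins and G1/S genes 2 and 5 of 18, and DNA damage genes 5 and 4 of 14. The mitochondrial genome had 0 higher and 0 lower of 1, small nucleolar RNAs 6 and 2 of 47, the Ty pattern 24 and 21 of 351, a-specific mating genes 4 and 0 of 7, alpha-specific 0 and 0 of 4, sporulation 5 and 1 of 10, and flocculation 4 and 1 of 8. Adjusted over the list alone, the counts were equal in 17 of the 29 lists and differed by at most 3 in the others, apart from the Ty pattern, with 17 and 12.

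The third comparison set the quantum dots side by side, at doses that differed, 10 and 100 µg/mL. Cytosolic ribosomal protein genes fell and heat shock genes rose with both, whereas proteasome genes were lower with CdSe/ZnS and higher with InP/ZnS. With the length trend removed, the ribosomal list lost its call with CdSe/ZnS (14 of 135 lower) and kept it with InP/ZnS (83 lower, adjusted p = 5.08e-52, Fisher's exact test). The proteasome list lost its call there with CdSe/ZnS (7 lower, adjusted p = 0.473, Fisher's exact test) and with InP/ZnS (5 higher, adjusted p = 0.553, Fisher's exact test). It was also lost in both with the normal test once centred. TMA10, a stress-induced gene of a ribosome-associated protein, fell by 1.36 with CdSe/ZnS and rose by 1.67 with InP/ZnS on the log2 scale in the authors' deposited table, a difference of -3.03 with a standard error of 0.35 (q = 8.47e-15). Of 6290 genes tested in both, 427 were higher with both and 931 lower with both. Opposite calls were made for 303 genes, 295 of them lower with CdSe/ZnS and higher with InP/ZnS, and 8 the other way.

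Lists drawn independently would share 145 higher and 481 lower genes, and would hold 665 and 104.7 genes in the opposite directions. Across these genes, which are not independent replicates, Pearson's r between the fold changes was 0.59 and Spearman's rho 0.58. Both comparisons use the same untreated cells, which alone gives a positive correlation. In 5443 genes with an implied standard error under 0.5 in both, a limit set after the data were seen, the covariance was 0.228 and r was 0.64. Simulated unchanged groups against a shared control gave a covariance of 0.0319 and r of 0.47 with a share of 0.5 of the variance placed in the control, and 0.0637 and 0.94 with all of it there; that share is an assumption. Their calls, made by the normal test, overlapped in at most 1 gene per direction in 100 simulations. With no real effect put in, few genes can pass at all, so this cannot show how far a shared control raises the overlap. Part of the excess may come from the shared untreated libraries, which could not be split.

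**Figure D3:**
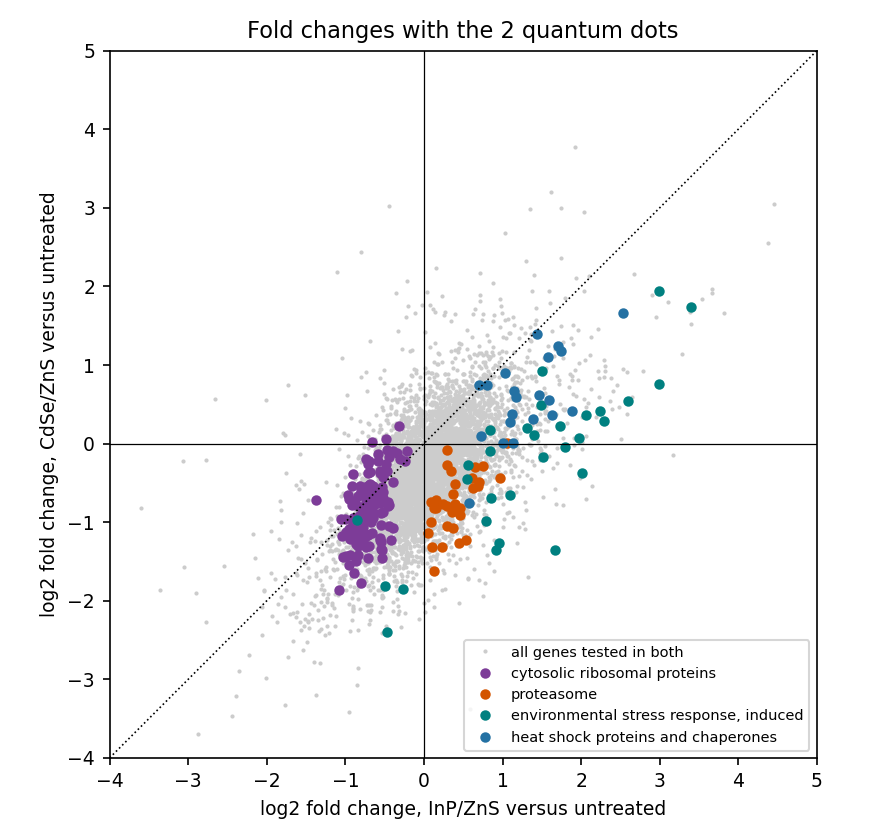
Log2 fold change against untreated cells with CdSe/ZnS (vertical axis) and InP/ZnS (horizontal axis) of each gene tested in both, with 4 gene lists in colour and equal changes on the dotted diagonal; 7 genes lie outside the plotted range. Proteasome genes (orange) have a median of -0.79 on the vertical axis and 0.37 on the horizontal axis.

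The difference between the fold changes passed its own test in 20 genes higher and 752 lower with CdSe/ZnS, at a median difference of -0.41 over all genes. After each comparison was centred on its median, also a later choice, 62 were higher and 130 lower. SPG4, a stationary phase gene, differed by -3.02 with a standard error of 0.33 (q = 1.03e-16), CYC7 by -3.31 with 0.42 (q = 6.47e-12) and YNR034W-A by -2.76 with 0.35 (q = 6.47e-12). YBR090C, which shares a locus with another entry, differed by -2.70 with 0.80 (q = 0.012) and did not pass once centred (q = 0.0949). In the other direction MEP2 was higher with CdSe/ZnS by 1.76 with a standard error of 0.33 (q = 1.07e-05), OAR1 by 1.41 with 0.37 (q = 0.00362), GPB1 by 1.35 with 0.33 (q = 0.00135) and SRO9 by 1.10 with 0.30 (q = 0.00518). OLI1, a mitochondrially encoded ATP synthase subunit gene, differed by 7.06 with a standard error of 1.68 (q = 0.00107), though it was called in neither comparison by the authors' q (0.0521 with CdSe/ZnS and 0.383 with InP/ZnS).

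Of the 303 genes called in opposite directions, 243 passed the test of the difference, which uses the same fold changes and so is no independent support. GPX1, a glutathione peroxidase gene, stood at -1.26 with CdSe/ZnS and 1.18 with InP/ZnS in the authors' deposited table, STF2 at -1.35 and 0.92, MSC1 at -0.37 and 2.01, and HSP26 at -1.27 and 0.96. OM45, a mitochondrial outer membrane protein gene, stood at 0.498 and 2.39 times its untreated level in the authors' deposited table. With CdSe/ZnS, GPX1 passed the normal test as deposited but not relative to the median, at -0.92. MSC1 passed it in neither form and stood at -0.02 relative to the median. YNL194C, YBR285W and YDR381C-A stood at -1.06 and 1.21, -2.03 and 0.45, and -1.60 and 0.64 in the authors' deposited table. With the normal test on fold changes as deposited, chosen after the data were seen, opposite calls numbered 39, with 143 genes higher and 375 lower with both. With the same test centred on the median of each comparison, likewise chosen after the data were seen, they numbered 15, with 249 higher and 329 lower.

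Among the lists, proteasome genes passed the test of the difference in 29 of 34 cases, all lower with CdSe/ZnS (adjusted p = 1.45e-20, Fisher's exact test). The induced stress response passed in 24 of 30 (adjusted p = 6.59e-16, Fisher's exact test) and the respiratory chain in 22 of 37 (adjusted p = 1.77e-10, Fisher's exact test), in the same direction. PRE6 differed by -1.74 with a standard error of 0.31 (q = 3.55e-06). COX12 differed by -1.83 with 0.40 (q = 0.000263) and CTT1 by -1.90 with 0.33 (q = 2.05e-06). Those list counts used differences as deposited, and centred counts are not given here. Once centred, PRE6, PRE9, PUP1, COX9, COX12, CYC7, CTT1, PGM2 and GLC3 kept their call. SCL1, RPN4, RPN8, RPT6, RPT4, COX8, NDI1, QCR9, GPH1 and HXK1 lost it. Median differences as deposited of -1.17 for proteasome, -1.67 for stress response and -1.03 for respiratory chain genes lay below all 10000 random lists. Centred, they were -0.76, -1.26 and -0.61. Centring moves a list and its random lists alike, so their place below the random lists is no check on it. Oxidative stress defence passed in 10 of 27 (adjusted p = 0.00863, Fisher's exact test), TRX2 among them at -1.13 with 0.32 (q = 0.00728), a call lost once centred (q = 0.251). Cytosolic ribosomal protein genes passed in 2 of 135 and heat shock genes in 6 of 21, both lower with CdSe/ZnS, at median differences of -0.12 and -0.74. The heat shock list was not enriched for such genes (adjusted p = 0.172, Fisher's exact test). The share of lower ribosomal genes, 1.5%, was below the 12.2% of other genes (adjusted p = 0.000229, Fisher's exact test). Their median difference already lay above all of 10000 random lists as deposited. It turned to 0.30 once each comparison was centred and to 0.55 with the length trend removed, again above all of them. The median difference of heat shock genes was -0.33 centred, within the central 95% of random lists, and -0.32 with the length trend removed, below it. The 2 tables were normalised separately: their untreated values differed by a median of 0.19 on the log2 scale over 5630 genes. The standard error of a difference makes no allowance for the control the comparisons share, so it is too large where the control varies.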

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

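The tests on the longest genes, on small nucleolar RNAs and on scaling in the proteasome and respiratory chain lists were chosen after their results were seen; the others were set before their tested values were seen, but after the raw medians of the lists and the trend with length. These results stand apart because the test of the difference between the quantum dots was passed: by 20 genes higher and 752 lower with CdSe/ZnS, and by 22 respiratory chain, 24 stress response, 10 oxidative stress, 29 proteasome and 1 mitochondrial genome members. The oxidative stress list had a centred median difference of -0.17, at percentile 21.9 of random lists. The stress response list had one of -1.26, below all 10000 random lists. Centring moves a list and its random lists alike, so these places in effect repeat those of the differences as deposited.

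A first pattern is the excess of lower genes with CdSe/ZnS, 2759 against 606. The authors' scaling may contribute: the sum of FPKM times coding length fell by 0.31 on the log2 scale from untreated to CdSe/ZnS, close to the median of -0.35, and 14 entries at the ribosomal DNA had too many fragments in this table, against 0 in the other. Gene length may contribute too, since the longest genes, of at least 2106 bp, had a median of -0.064 and the shortest, up to 612 bp, one of -0.71. A loss of most messenger RNAs in these cells was not tested and stays open, since FPKM carry no absolute scale. The number of lower calls therefore cannot be read as the number of genes with less RNA per cell.

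A second pattern is the lower level of proteasome and respiratory chain genes with CdSe/ZnS than with InP/ZnS. A single scaling factor per table moves all genes alike and so would leave a list among random lists matched on expression. The median differences of -1.17 and -1.03 lay below their central 95%. Both lists were flagged by counts of these same differences, so this repeats those counts and is no separate test. It shows only that these lists differ from other genes of like level, which a single factor alone would not give. A length trend is argued against as the whole cause by median differences of -0.72 and -0.41 once it was removed, again below the random lists. Here too the lists came from the same differences, so this is no independent support. With the trend removed, the proteasome list lost its call in each comparison, with 7 members lower with CdSe/ZnS and 5 higher with InP/ZnS. The respiratory median was then 0.06 with CdSe/ZnS and 0.45 with InP/ZnS. A candidate explanation is a response that differs between the quantum dots, but dose and core differ together, and growth state at harvest was not analysed here, so these stay open.

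Another pattern is RNA of the mitochondrial genome, whose 9 tested entries with CdSe/ZnS had log2 fold changes of at least 5.31 and a median of 7.89, 5 of them not past the threshold; the authors' deposited table lists 15S_rRNA at 0.339 FPKM untreated and 361 with CdSe/ZnS, and at 0.266 and 0.474 in the InP/ZnS table. Less complete poly(A) selection may play a part: small nucleolar RNAs, which lack a tail, had a median of 0.34 and a median difference from InP/ZnS of 0.25, each above all 10000 random lists. They passed as a list with a floor of 10 FPKM, with a log2 fold change of at least 1 and with the uncentred normal test, but not in the main or the centred test. Their upper quartile of 1.06 lay far below the mitochondrial values, but their untreated median of 57.4 FPKM would hide a small added amount. With CdSe/ZnS, 14 entries at the ribosomal DNA had too many fragments, against 0 with InP/ZnS. LSR1, SCR1 and TLC1, non-coding RNAs chosen after their values were seen, rose by 1.61, 0.66 and 0.85 on the log2 scale with CdSe/ZnS. With InP/ZnS they stood at -0.23, -0.26 and -0.05. RPR1 did not pass with either (0.51 and -0.23), and NME1 stood at 1.16 and 0.96. What rose with CdSe/ZnS alone goes the way of less complete selection, but no test was run on it, so its part stays undecided. Untreated and InP/ZnS cultures without mitochondrial DNA are another candidate, which could raise the retrograde genes CIT2 and DLD3 there. Relative to the median CIT2 stood at -0.74 and DLD3 at -0.47 with CdSe/ZnS. Only the first passed the centred test, which leaves this candidate undecided. OLI1, the only tested mitochondrial entry in the InP/ZnS table, stood at 5.99995 FPKM untreated and 10.5821 FPKM with InP/ZnS. Some RNA of that genome was thus listed in both conditions, but a single entry of low level cannot decide the question. Values per library were not analysed here, so a rise carried by 1 of the pooled libraries stays open. A biological effect of CdSe/ZnS on mitochondrial RNA, which was not tested, stays open too.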

How the results depend on the processing

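The uncentred normal test, removal of the length trend, the limit on the standard error and, between the quantum dots, centring were chosen after the data were seen. No paired analysis was possible because no column carried a replicate; for the same reason the replicate block, leaving out each replicate, DESeq2 and other pseudocounts were not run. With an absolute log2 fold change of at least 1, calls fell to 96 higher and 906 lower for CdSe/ZnS and to 295 and 139 for InP/ZnS, and enriched InP/ZnS lists to 3 higher and 1 lower. For CdSe/ZnS the respiratory chain, amino acid, purine, ergosterol, proteasome and multidrug lists lost their call at that fold, and cell wall, core histones, small nucleolar RNAs and sporulation gained one. Centring with the normal test gave 862 lower genes for CdSe/ZnS, 501 higher and 530 lower for InP/ZnS, and 6 lists higher for InP/ZnS. Uncentred, the same test gave 280 higher for CdSe/ZnS and 592 and 417 for InP/ZnS, so the test accounts for the smaller InP/ZnS counts and centring for the CdSe/ZnS split. With the length trend removed, 695 genes were lower for CdSe/ZnS, with 4 lists higher and 3 lower, and 495 and 520 genes passed for InP/ZnS.

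Between the quantum dots, q under 0.01 left 279 genes higher with both, 159 in opposite directions, and 7 higher and 343 lower with CdSe/ZnS by the test of the difference. The uncentred normal test gave 143 higher and 375 lower with both and 39 opposite, the centred one 249, 329 and 15, and the one with the length trend removed 227, 286 and 12. The fall from the main counts thus came mostly with the test for opposite calls and for those lower with both. The test of the difference is a normal test throughout: centring gave 62 higher and 130 lower, and length removal 55 and 106. For the stricter q and the length trend, the cause was not tested beyond the setting itself. The floors run here moved these counts by under 1.5 times; the authors' own lists and the new adjustment were not run between the quantum dots. Of 80 list results for CdSe/ZnS, 23 lost and 20 gained their call, and of 75 for InP/ZnS, 25 lost and 5 gained it, with 0 reversed. Results for named genes kept their call, or the lack of one, in 1132 of 1271 cases and 1091 of 1234, and 0 reversed. Only centring and removal of the length trend change the fold itself, so a reversal was possible only there. The floor of 1 FPKM and the new adjustment left all 160 named genes for CdSe/ZnS and all 155 for InP/ZnS as they were, which raises these shares. Depth is unknown, so no limit of detection can be given.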

Other observations

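The genes in this part were chosen after their values were seen, and no test of an explanation was run on them. In the authors' deposited table MIG2, a glucose-induced repressor gene, fell with both quantum dots, by 1.70 with CdSe/ZnS and by 1.77 with InP/ZnS on the log2 scale. SUC2, invertase, rose by 0.42 and by 1.17 in the authors' deposited table. The low-affinity hexose transporter gene HXT1 stood at -0.28 (q = 0.142) with CdSe/ZnS and fell by 0.94 with InP/ZnS in the authors' deposited table, while HXT4 fell to 0.501 times its untreated level with CdSe/ZnS, a call lost with the normal test relative to the median, and stood at 0.36 (q = 0.0506) with InP/ZnS. CTR1, the copper transporter gene, which shares a locus with another entry, rose by 0.56 and by 2.04 in the authors' deposited table.

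In the authors' deposited table LSR1, the U2 spliceosomal RNA, rose from 39.4 to 120 FPKM with CdSe/ZnS, SCR1, the RNA of the signal recognition particle, from 56.0 to 88.5 FPKM, and TLC1, telomerase RNA, from 13.2 to 23.7 FPKM. With InP/ZnS these stood at log2 fold changes of -0.23, -0.26 and -0.05 in the authors' deposited table, none past the threshold. RPR1, the RNA of RNase P, did not pass with either (0.51 and -0.23 in the authors' deposited table), and NME1 rose by 1.16 and 0.96, calls lost with the normal test, centred or not.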
